A study of Homo sapiens with 12 samples.

How the data were processed

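The deposited file is a single table of RPKM values for 48085 genes in 12 libraries, with gene symbols, positions and lengths, per the file headers. Libraries were prepared from total RNA by a SMARTer mRNA-Seq method, per the labels' protocols, and the genome build is hg38, per the submitters' processing notes. The aligner, the counter, the annotation release and whether counting used strand are not given in the sources used here, so overlapping and antisense genes are treated as uncertain. Libraries are TFK1 cells of 4 groups (control, radiation at 6 Gy, surufatinib at 4.33 ng/ml, and both) with 3 replicates per group, taken after 24 h, per the labels.

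The values imply the depth. Each RPKM value times the gene length is a whole number of reads at 1 scale per library, with 100.0% of values within 0.05 of a whole number, which gives 33.5 M to 63.9 M assigned reads per library. Mitochondrial genes hold 13.85% to 18.46% of them. Between 74.3% and 75.9% of the low recovered numbers are even, so the mates of a read pair appear to have been counted separately and the number of fragments is lower. Between 30800 and 34438 genes per library had a value above 0. In 28 symbols a spreadsheet had turned the name into a date, and these were left as they stand; 48083 names are distinct, and 31095 are in GENCODE release 29, which was used for gene type and GC content only.

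Because the file holds RPKM and no raw counts, the test was limma (version 3.58.1, R 4.3.3) on log2(RPKM + 1), with a filter of 1 RPKM in at least 3 of the 12 libraries (15387 genes), 1 fit of all 4 groups (8 residual degrees of freedom, 3.36 prior degrees of freedom), an intensity trend in the variance and Benjamini-Hochberg adjustment at 0.05 within each comparison. Of the tests that model counts only voom was run, as an alternative on the recovered reads. The comparisons were radiation, surufatinib and combination against control, combination against radiation, combination against surufatinib, and the interaction (combination minus surufatinib) minus (radiation minus control). The median SE of a log2 fold change was 0.07, and 0.098 for the interaction. Depth differed by less than 2-fold between libraries and the SE rests on the spread between replicates.

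Before the data were examined, 33 gene lists with 836 symbols were fixed, of which 833 were found, 54 under an older name. Lists with at least 5 tested members, 27 in number, were tested with limma's camera at a preset correlation of 0.01. It was run again with an estimated correlation, and p-values were adjusted over the lists of a comparison. Limma's fry was also run and is given only where named. Its directional test asks whether members move on balance one way, and its mixed test whether they change either way, neither against other genes. The lists covered p53 targets, G2/M and mitosis, replication and E2F targets, histones, double-strand break repair, apoptosis, interferon-stimulated, NF-kB and inflammatory genes, macrophage-recruiting and M2-polarizing factors, surufatinib targets, other receptor tyrosine kinases, angiogenic ligands, ERK output, integrated stress response, unfolded protein response, cholesterol and fatty acid synthesis, hypoxia and glycolysis, NRF2 targets, xenobiotic response, heat shock, epithelial-mesenchymal transition, epithelial and cholangiocyte identity, senescence-associated factors, antigen presentation, autophagy and lysosome, ferroptosis, ribosomal proteins, mitochondrially encoded genes, and markers of macrophages, lymphocytes, fibroblasts, endothelium and hepatocytes.

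Genes are named by a fixed rule. From each comparison come the 10 largest rises and 10 largest falls (5 and 5 for combination against radiation, combination against surufatinib and the interaction) among genes past the threshold with a proper symbol, a mean of at least 2 RPKM in the higher group and, for pairs of groups, all 3 libraries of the higher group above all 3 of the lower. From each list come up to 4 members past the threshold with the largest change, or up to 2 with the smallest p as values. CDKN1A, MDM2, CCNB1, MKI67, CSF1, CCL2, IL6, VEGFA, TGFB1 and the target receptors are always given. Small RNA genes and pseudogenes that the rule selects are mentioned together, and 2 genes at the ALDH1A3 locus with clone names were called in the interaction and are named because that count is small.

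The fit was tested on simulated data in 10 simulations of 200 changed genes per comparison, on 15165 to 15224 genes. For radiation against control 77.8% of 1.5-fold, 90.6% of 2-fold and 97.9% of 4-fold changes were recovered, with 3.7% of calls false; for surufatinib against control the shares were 75.9%, 93.9% and 98.6% (5.4% false), and for combination against control 79.5%, 91.6% and 98.3% (4.8% false). For combination against radiation they were 78.8%, 92.5% and 98.3% (6.1% false), for combination against surufatinib 79.4%, 92.2% and 98.2% (6.2% false), and for the interaction 55.4%, 82.8% and 95.4% (5.4% false). The simulated reads gave genes of similar level the same spread and held no deviating library. Both differ from the real data, so these shares may be too favourable. The adjusted threshold also depends on how many genes change, so the shares hold for 200 changed genes only.

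Alternatives were a pseudocount of 0.1 or 0.5, no filter, a filter of 5 RPKM, TMM factors computed on the RPKM values, quantile normalization, a replicate block, robust variance moderation, array weights, only the 6 libraries compared, and each library left out in turn. Chosen after seeing the data were voom on the recovered reads, removal of a length trend or of a length and GC trend from each library, RPKM without mitochondrial reads, and the fit without radiation replicate 1 and combination replicate 1. The length and GC setting tested only the 12376 genes with a GC value. The filter of 5 RPKM tested only 7421 genes, and the fit with no filter 48085. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.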

Results

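RNA was sequenced from TFK1, an established human cholangiocarcinoma (bile duct cancer) cell line, under 4 conditions of 3 libraries each. The cells were untreated controls, irradiated with 6 Gy, exposed to 4.33 ng/ml surufatinib, or given both treatments, and RNA was taken after 24 h. The unit of the drug dose is as the labels give it and could not be checked from these data. Surufatinib is a small-molecule inhibitor of the vascular endothelial growth factor receptors, FGFR1 and the CSF1 receptor. The design asks how the drug alters the response of these cells to radiation, and the study also names macrophages, which were not among the cultures described in the labels. Reads assigned to genes per library numbered 54.5 M, 49.2 M and 63.9 M in the controls, 33.5 M, 50.5 M and 60.8 M after radiation, 40.7 M, 54.0 M and 51.2 M after surufatinib, and 34.0 M, 51.6 M and 47.9 M after the combination. Of 48085 genes in the table, 15387 reached 1 RPKM in at least 3 libraries and were tested. Fold changes below are log2 values on the RPKM + 1 scale, which understates the change of low genes, and each is given with its standard error (SE). The labels call the libraries biological replicates without saying whether they came from separate cultures, so p-values measure only the spread between these libraries.

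The first principal component, with 39.1% of the variance, parted the 6 libraries with drug from the 6 without, and the second, with 19.7%, parted irradiated from non-irradiated libraries. Radiation replicate 1 stood apart from radiation replicates 2 and 3. Its chi-square per degree of freedom against them was 32.16 and 30.53, against 5.4 between the other pair, and its mitochondrial share of reads was the highest of the 12 libraries, at 18.46%. By chi-square, combination replicate 3 stood apart from its group to a smaller degree, at 16.8 and 12.18 against 4.77 between combination replicates 1 and 2. The correlation of log2 levels over tested genes gave another order. There combination replicate 1 was less close, at 0.9936 and 0.9929 against 0.9946 between combination replicates 2 and 3.

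**Figure D1:**
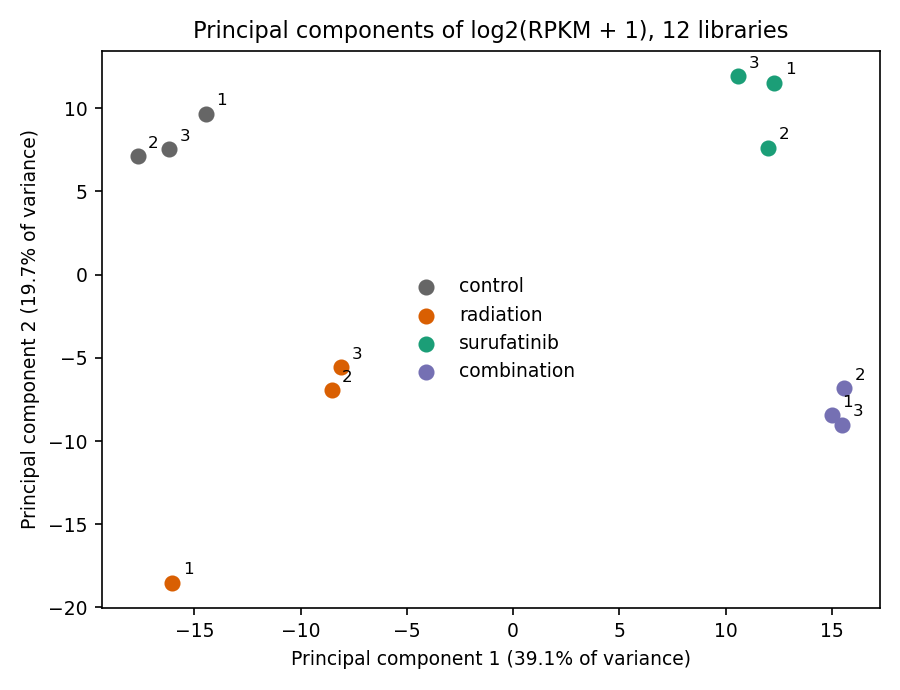
First and second principal components of log2(RPKM + 1) over 15387 genes, with 39.1% and 19.7% of the variance; each point is 1 of 12 libraries, coloured by treatment and numbered by replicate. The drug separates libraries along the first axis and radiation along the second, and radiation replicate 1 lies below the other 2 of its group.

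Radiation alone raised p53 target genes and lowered genes of mitosis. CDKN1A, which encodes a cyclin-dependent kinase inhibitor (chromosome 6, 36676460 to 36687339), went from 26.0 ± 1.65 to 57.1 ± 5.78 RPKM (SD, n = 3), a log2 change of 1.1 ± 0.07 (SE; limma adjusted p = 1.31e-05). MKI67, the source of the proliferation marker Ki-67 (chromosome 10, 128096659 to 128126385), went from 84.6 ± 0.965 to 51.3 ± 2.13 RPKM, a log2 change of -0.71 ± 0.054 (limma adjusted p = 5.61e-05). In all, limma called 1665 genes at a Benjamini-Hochberg adjusted p under 0.05, 855 higher and 810 lower, and most changes were small: 67 rose and 37 fell by at least 1.5-fold on this scale. The balance of direction turned with scaling, to 744 higher and 984 lower under TMM factors and 1084 and 715 for RPKM without mitochondrial reads. Beside CDKN1A, the largest rises included TNFRSF6B, a secreted decoy receptor for Fas ligand (1.12 ± 0.11; its exons overlap RTEL1-TNFRSF6B and ARFRP1, so its reads are uncertain), the keratin-associated gene KRTAP2-3 (1.03 ± 0.084), BTBD19 (0.98 ± 0.083), the carboxypeptidase gene CPA4 (0.96 ± 0.081) and the retinaldehyde dehydrogenase gene ALDH1A3 (0.91 ± 0.045). The largest falls included H1FX, a linker histone gene (-0.74 ± 0.071), PHGDH, which encodes an enzyme of serine synthesis (-0.71 ± 0.11), FLOT1 (-0.70 ± 0.082) and HMGB2 (-0.70 ± 0.07), and also the small RNA genes MIR4292 and RNU6-9, whose short length makes RPKM values uncertain. That all 3 libraries of the higher group lay above all 3 of the lower was a condition for naming these genes, not a separate result.

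Of 38 tested p53 target genes, 33 rose, 0 fell and 5 did not pass (34 and 0 adjusted over the list alone). The list median was 0.385 (camera adjusted p = 1.43e-28, and adjusted p = 0.00343 with an estimated correlation). FDXR, a mitochondrial reductase gene (0.98), PLK3 (0.85) and TP53INP1 (0.82) led it after CDKN1A. MDM2, the p53 ubiquitin ligase gene, changed by 0.24 ± 0.054 (limma adjusted p = 0.0158), a call that was lost without control replicate 1 (adjusted p = 0.0587), without control replicate 3 (0.0525) and when only the 6 libraries compared were fitted (0.0913). Its alternatives ran from 0.00122 to 0.0913. Of 35 G2/M and mitosis genes, 0 rose and 33 fell (0 and 34 adjusted over the list alone), with a median of -0.443 (camera adjusted p = 1.55e-32, and adjusted p = 0.00343 with an estimated correlation). Among them were the kinesin gene KIF20A (-0.66), the Aurora kinase gene AURKB (-0.66), CENPF (-0.62) and cyclin B1, CCNB1 (-0.55). Of 37 DNA replication and E2F target genes 1 rose and 16 fell (1 and 25 adjusted over the list alone), with the flap endonuclease gene FEN1 (-0.50) among those lower. The median was -0.225 (camera adjusted p = 2.8e-12, and adjusted p = 0.139 with an estimated correlation). The 16 became 10 without control replicate 1 and 8 without control replicate 3. Of 36 double-strand break repair genes, 0 rose and 5 fell (0 and 6 adjusted over the list alone), FANCI (-0.36) and POLQ (-0.32) most, with a median of -0.111 (camera adjusted p = 0.000848, and adjusted p = 0.153 with an estimated correlation). The 5 became 3 without control replicate 1, radiation replicate 2 or combination replicate 2 and 2 without control replicate 3, and the list was not called among genes of at least 5 RPKM (camera adjusted p = 0.062; range over the alternatives 2.48e-06 to 0.062).

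Several smaller groups also moved with radiation. Interferon-stimulated genes were higher: 10 of 23 rose and 0 fell (12 and 0 adjusted over the list alone), with a median of 0.194 (camera adjusted p = 2.85e-05, and adjusted p = 0.0401 with an estimated correlation), as in IFIT3 (0.38 ± 0.067) and IFIT2 (0.28 ± 0.051). The 10 became 5 without any 1 of control replicates 1, 2 and 3, and the camera call was lost among genes of at least 5 RPKM (adjusted p = 0.0548; range 1.91e-05 to 0.0548). Cholesterol and fatty acid synthesis genes were lower, with 0 of 31 higher and 10 lower (0 and 14 adjusted over the list alone), as in the sterol sensor gene INSIG1 (-0.52), SREBF1 (-0.38), FDFT1 (-0.38) and SCD (-0.37). Their median was -0.175 (camera adjusted p = 2.22e-09, and adjusted p = 0.0401 with an estimated correlation). Of 14 heat shock genes 8 fell and 0 rose (10 and 1 adjusted over the list alone), HSPA1B (-0.51) most. Median change was -0.187 (camera adjusted p = 1.26e-06, and adjusted p = 0.0851 with an estimated correlation). Without radiation replicate 1, 1 rose. Of 22 unfolded protein response genes 7 fell and 0 rose (9 and 0 adjusted over the list alone), among them HERPUD1 (-0.66), HYOU1 (-0.43) and MANF (-0.41). The median was -0.131 (camera adjusted p = 3.57e-06, and adjusted p = 0.153 with an estimated correlation).

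Among 12 angiogenic ligands 4 rose and 0 fell (6 and 0 adjusted over the list alone), including PDGFB (0.40) and endothelin, EDN1 (0.36). Their median was 0.152 (camera adjusted p = 0.00982, and adjusted p = 0.153 with an estimated correlation). Without radiation replicate 2 the median was 0.101 and the call was lost (camera adjusted p = 0.053), as it was among genes of at least 5 RPKM (0.0966; range 0.00192 to 0.0966). Of 9 senescence-associated secreted factors 4 rose and 0 fell, also adjusted over the list alone, with the urokinase gene PLAU (0.54) and TIMP1 (0.26) among them. Median change was 0.057 (camera adjusted p = 0.0128, and adjusted p = 0.153 with an estimated correlation). With no filter on low values the median was -0.011 and the call was lost (camera adjusted p = 0.731; range 0.00232 to 0.731). Integrated stress response genes were lower in 5 of 21 cases and higher in 0 (10 and 0 adjusted over the list alone). The median was -0.176 (camera adjusted p = 8.79e-05, and adjusted p = 0.153 with an estimated correlation). Ribosomal protein genes were lower in 6 of 35 cases and higher in 0 (19 and 0 adjusted over the list alone). Their median was -0.19 (camera adjusted p = 6.94e-10, and adjusted p = 0.334 with an estimated correlation). Both moved with radiation replicate 1: without it the medians were -0.095 and -0.098. The 5 integrated stress response genes became 2, 3 and 1 without control replicates 1, 2 and 3 and 3 without any 1 combination library. The 6 ribosomal protein genes became 1, 2 and 1 without those controls and 10 and 11 without radiation replicates 2 and 3. The whole count of 1665 fell to 986, 944 and 894 without control replicates 1, 2 and 3, to 1005 with no filter and to 652 when only the 6 libraries compared were fitted, and rose to 2852 with array weights.

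After surufatinib alone many cholesterol synthesis genes rose, and many integrated stress response and glycolysis genes fell. As lists these 3 were called at a preset correlation between genes but not at an estimated one (camera adjusted p = 0.0833, 0.201 and 0.217). The directional test of fry, which is not against other genes, gave adjusted p = 7.67e-06, 2.67e-05 and 0.000134 for them. DDIT3, the stress transcription factor gene (chromosome 12, 57516588 to 57520517), went from 71.2 ± 5.73 to 23.9 ± 2.09 RPKM (SD, n = 3), a log2 change of -1.54 ± 0.16 (limma adjusted p = 5.69e-05; its exons overlap MARS, and the microRNA gene MIR616 lies within it). HERPUD1, which encodes a protein of endoplasmic reticulum quality control (chromosome 16, 56932048 to 56944863), went from 19.2 ± 0.535 to 6.44 ± 0.104 RPKM (-1.44 ± 0.061, limma adjusted p = 2.64e-07). By limma 4937 genes changed, 2160 higher and 2777 lower, of which 157 rose and 174 fell by at least 1.5-fold. Under TMM factors the split was 2624 higher and 2429 lower. The largest rises included ALDH1A3 (chromosome 15, 100877714 to 100916626), from 96.8 ± 4.36 to 250 ± 3.78 RPKM (1.36 ± 0.045), PLAU (1.29 ± 0.066; its exons overlap C10orf55), TNFRSF6B (1.46 ± 0.11), KRTAP2-3 (1.22 ± 0.084), the 14-3-3 sigma gene SFN (1.19 ± 0.12) and C11orf68 (1.15 ± 0.1), and the aquaporin pseudogenes AQP7P3 (1.5) and AQP7P1 (1.26), whose reads near-identical copies can share. Beside DDIT3 and HERPUD1, the largest falls included the immediate early gene EGR1 (-1.23 ± 0.1) and ID2, an inhibitor of helix-loop-helix transcription factors (-1.2 ± 0.083), and several small RNA genes and pseudogenes. With a filter of 5 RPKM, which tested only 7421 genes, 2920 were called.

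Of 31 cholesterol and fatty acid synthesis genes, 22 rose and 0 fell, also adjusted over the list alone, with a median of 0.283 (camera adjusted p = 5.37e-11, but adjusted p = 0.0833 with an estimated correlation). FDFT1 (0.90 ± 0.06), MSMO1 (0.82 ± 0.07), HMGCS1 (0.76 ± 0.075) and INSIG1 (0.70 ± 0.087) rose most. Of 21 integrated stress response genes, which follow the transcription factor ATF4, 0 rose and 16 fell (0 and 18 adjusted over the list alone). Median change was -0.346 (camera adjusted p = 9.12e-08, and adjusted p = 0.201 with an estimated correlation). Next to DDIT3 the largest falls were those of CHAC1, a glutathione-degrading enzyme gene (-1.02 ± 0.077), the serine synthesis gene PSAT1 (-0.69 ± 0.057) and asparagine synthetase, ASNS (-0.68 ± 0.044). Of 22 unfolded protein response genes 7 fell and 0 rose, also adjusted over the list alone, DNAJC3 (-0.61) and SEL1L (-0.50) after HERPUD1. The median was -0.112 (camera adjusted p = 0.0102, and adjusted p = 0.566 with an estimated correlation). Without radiation replicate 1 the 7 became 11 and 1 rose. Of 23 hypoxia and glycolysis genes 0 rose and 15 fell (1 and 16 adjusted over the list alone), led by the glucose transporters SLC2A1 (-1.0 ± 0.1) and SLC2A3 (-0.75 ± 0.081), with ANKRD37 (-0.83) and hexokinase 2, HK2 (-0.51). Their median was -0.264 (camera adjusted p = 3.7e-06, and adjusted p = 0.217 with an estimated correlation). Without radiation replicates 1 or 2, 1 rose. Of 21 NRF2 target genes 10 rose and 3 fell (11 and 3 adjusted over the list alone): the transporter ABCC3 (1.02), NQO1 (0.77) and ferritin light chain, FTL (0.67), were higher and the cystine transporter SLC7A11, also an ATF4 target, lower (-0.53). Median change was 0.138 (camera adjusted p = 0.0102, and adjusted p = 0.291 with an estimated correlation).

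More proliferation genes rose than fell with the drug alone, by small amounts, and neither of their 2 lists was called with an estimated correlation (camera adjusted p = 0.235 and 0.566). By fry's directional test, not against other genes, the adjusted p was 0.000616 and 0.0302. Of 35 G2/M and mitosis genes 18 rose and 1 fell (18 and 2 adjusted over the list alone), as in AURKB (0.50 ± 0.087), CDK1 (0.41 ± 0.046) and CCNB1 (0.30 ± 0.056), while MKI67 did not pass (-0.11 ± 0.054, limma adjusted p = 0.148). The median was 0.208 (camera adjusted p = 0.00017, and adjusted p = 0.235 with an estimated correlation). Of 37 DNA replication and E2F target genes 14 rose and 3 fell (16 and 3 adjusted over the list alone), with thymidylate synthase, TYMS (0.69 ± 0.072), and GINS1 (0.44 ± 0.057) among those higher. Their median was 0.155 (camera adjusted p = 0.00248, and adjusted p = 0.566 with an estimated correlation). The 14 became 9 without control replicate 1. Of 38 p53 target genes 23 rose and 2 fell (23 and 3 adjusted over the list alone), CDKN1A (0.97 ± 0.07), GADD45A (0.73), BTG2 (0.57) and FDXR (0.57) most. Median change was 0.228 (camera adjusted p = 2.32e-06, and adjusted p = 0.201 with an estimated correlation). MDM2 stood at 0.15 ± 0.054 (limma adjusted p = 0.0498), a call lost without control replicates 1, 2 and 3 (0.125, 0.0909 and 0.106), surufatinib replicates 1, 2 and 3 (0.0607, 0.134 and 0.113), combination replicates 1, 2 and 3 (0.0642, 0.068 and 0.0631) or radiation replicate 3 (0.0519), in a range of 7.81e-05 to 0.134 over its alternatives. The 2 lower p53 targets became 1 without control replicate 2 or surufatinib replicate 1, and the 1 lower mitosis gene became 2 without control replicate 1 and 4 without radiation replicate 1.

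Of 10 NF-kB and inflammatory genes 5 rose and 1 fell (5 and 2 adjusted over the list alone), including the cytokine gene LIF (1.12) and the NF-kB inhibitor NFKBIA (0.58), and this call was lost without radiation replicate 1 (camera adjusted p = 0.0508) and among genes of at least 5 RPKM (0.0928, median 0.379; range 0.00929 to 0.0928). The median was 0.221 (camera adjusted p = 0.0202, and adjusted p = 0.291 with an estimated correlation). The 1 fall became 2 without radiation replicates 1 or 3 and 0 without any 1 of the 3 control and 3 combination libraries and surufatinib replicates 2 and 3. Among 29 ERK pathway output genes 5 rose and 12 fell (6 and 12 adjusted over the list alone; median -0.11, camera adjusted p = 0.273): EGR1 and FOS (-0.97) were lower while LIF and PLAUR (0.78) were higher. Fold changes after surufatinib also went with gene length, as libraries with drug gave lower values for long genes. The slope of log2 level on log2 exonic length lay between -0.0542 and -0.0102 in the 6 libraries with drug and between 0.011 and 0.0754 in the 6 without, highest in radiation replicate 1.

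**Figure D2:**
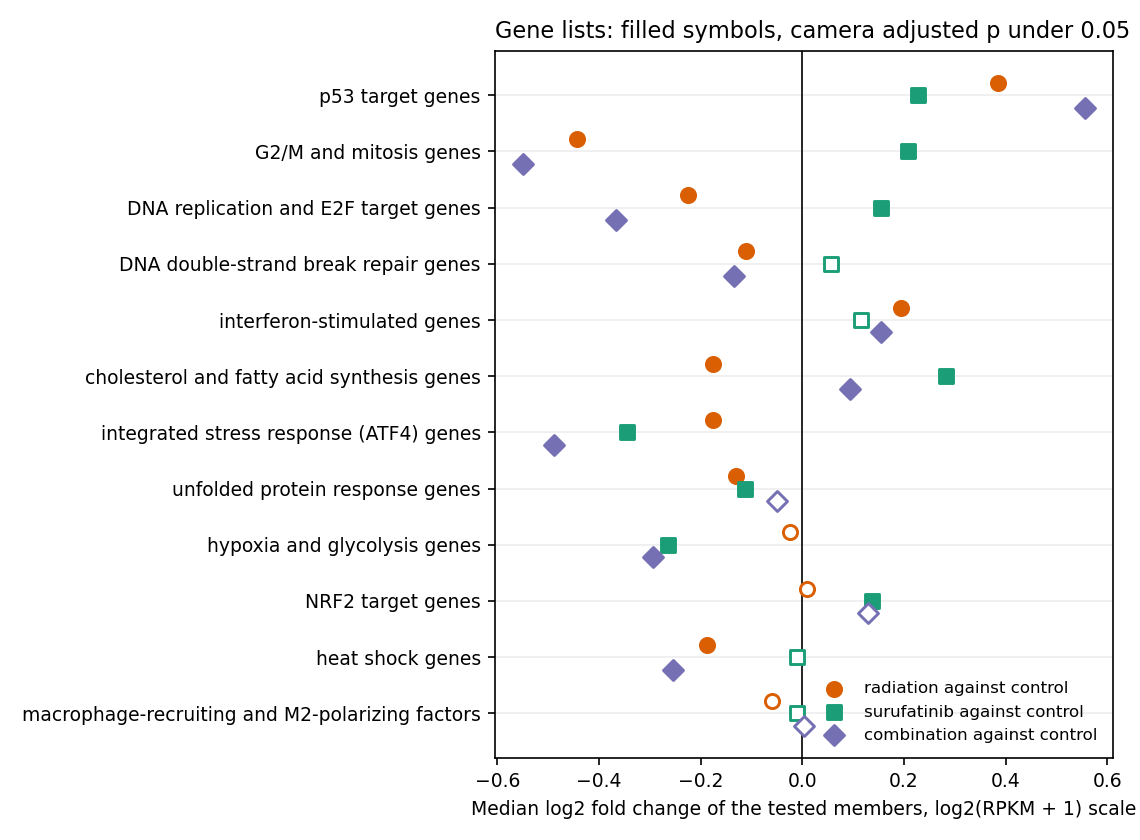
Median log2 fold change, on the RPKM + 1 scale, of the tested members of 12 gene lists after radiation (circles), surufatinib (squares) and the combination (diamonds), each against control; filled symbols have a camera adjusted p under 0.05 at a preset correlation. The p53 list lies at 0.385, 0.228 and 0.556, the G2/M list at -0.443, 0.208 and -0.549, and the cholesterol list at -0.175, 0.283 and 0.094.

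With both treatments p53 targets were higher, and mitosis, replication and ATF4-dependent genes lower, than in control cells. As lists the replication and ATF4-dependent genes were not called with an estimated correlation (camera adjusted p = 0.341 and 0.122). By fry's directional test, not against other genes, the adjusted p was 0.00013 and 4.24e-06. CDKN1A reached 82.4 ± 2.79 RPKM (SD, n = 3; 1.63 ± 0.07, limma adjusted p = 1.13e-07) and MKI67 dropped to 41.9 ± 0.822 RPKM (-1.0 ± 0.054, limma adjusted p = 3.61e-07). CD68, a lysosomal glycoprotein gene best known as a macrophage marker (chromosome 17, 7579467 to 7582113), went from 1.88 ± 0.201 to 7.66 ± 0.511 RPKM (1.59 ± 0.069, limma adjusted p = 1.13e-07). Its exons overlap those of RP11-186B7.4 and AC113189.5, so its reads are uncertain. The RNA-binding protein gene SFPQ (chromosome 1, 35176378 to 35193148) went from 150 ± 4.42 to 56.8 ± 1.58 RPKM (-1.39 ± 0.056, limma adjusted p = 1.13e-07). By limma 6144 genes changed, 2720 higher and 3424 lower, with 357 up and 338 down by at least 1.5-fold. With a filter of 5 RPKM 3451 of only 7421 tested genes were called. Other large rises were TNFRSF6B (2.08 ± 0.11), KRTAP2-3 (1.88 ± 0.084), SFN (1.6 ± 0.12) and PLAU (1.56 ± 0.066). Other large falls were EGR1 (-1.39 ± 0.1), HERPUD1 (-1.37 ± 0.061), DDIT3 (-1.36 ± 0.16), ACBD7 (-1.24 ± 0.086) and PHGDH (-1.11 ± 0.11).

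Of 38 p53 target genes 30 rose and 0 fell (32 and 0 adjusted over the list alone), with TP53I3 (1.24 ± 0.091), FDXR (1.15 ± 0.079) and BTG2 (1.07 ± 0.056) after CDKN1A, and MDM2 at 0.30 ± 0.054 (limma adjusted p = 0.00133). Their median was 0.556 (camera adjusted p = 4.36e-18, and adjusted p = 0.0157 with an estimated correlation). Of 35 G2/M and mitosis genes 0 rose and 34 fell (0 and 35 adjusted over the list alone), KIF20A (-1.03 ± 0.12) and CENPF (-0.99 ± 0.057) beside MKI67. Median change was -0.549 (camera adjusted p = 3.7e-18, and adjusted p = 0.0157 with an estimated correlation). Of 37 replication and E2F target genes 1 rose and 27 fell (2 and 28 adjusted over the list alone), TK1 (-0.98 ± 0.11) and the DNA polymerase gene POLA1 (-0.70 ± 0.052) among those lower. The median was -0.366 (camera adjusted p = 8.59e-08, and adjusted p = 0.341 with an estimated correlation). Of 36 double-strand break repair genes 2 rose and 15 fell (3 and 15 adjusted over the list alone), among them XRCC2 (-0.52), POLQ (-0.51) and BRCA1 (-0.41). Their median was -0.135 (camera adjusted p = 0.0138, and adjusted p = 0.412 with an estimated correlation). The camera call was lost among genes of at least 5 RPKM (adjusted p = 0.304, median -0.091) and with a length and GC trend removed (0.117, median -0.1), in a range of 1.47e-05 to 0.304. The 2 rises became 1 without control replicates 2 or 3 or combination replicate 3, and the 1 rise among replication genes became 2 without radiation replicates 1 or 3 or combination replicate 1.

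Of 21 integrated stress response genes 0 rose and 17 fell (0 and 18 adjusted over the list alone), CHAC1 (-0.92) and PSAT1 (-0.88) after DDIT3 and PHGDH. Median change was -0.489 (camera adjusted p = 1.57e-08, and adjusted p = 0.122 with an estimated correlation). Hypoxia and glycolysis genes showed 1 rise and 17 falls among 23 (1 and 20 adjusted over the list alone), SLC2A3 (-0.80) and SLC2A1 (-0.67) among them. The median was -0.293 (camera adjusted p = 2.48e-05, and adjusted p = 0.245 with an estimated correlation). Cholesterol and fatty acid synthesis genes showed 14 rises and 2 falls among 31, also adjusted over the list alone, with MSMO1 (0.71) and HMGCS1 (0.43) higher. Their median was 0.094 (camera adjusted p = 0.0085, and adjusted p = 0.395 with an estimated correlation). Interferon-stimulated genes showed 11 rises and 2 falls among 23, also adjusted over the list alone: IFIT3 (0.78) and TRIM22 (0.62) rose and SAMD9 (-0.58) fell. Median change was 0.155 (camera adjusted p = 0.012, and adjusted p = 0.22 with an estimated correlation). Without combination replicate 2 that median was 0.101, and the call was lost among genes of at least 5 RPKM (camera adjusted p = 0.535; range 0.00838 to 0.535). The 2 lower cholesterol genes became 1 without control replicates 2 or 3 or combination replicates 1 or 2, and the 1 higher hypoxia gene became 0 without any 1 control library or combination replicates 2 or 3. Of 14 heat shock genes 2 rose and 8 fell, also adjusted over the list alone. The median was -0.254 (camera adjusted p = 0.0473, and adjusted p = 0.428 with an estimated correlation). That call was lost with TMM factors (0.0633), without control replicate 1 (0.108), radiation replicate 2 (0.0503), surufatinib replicates 1, 2 and 3 (0.0548, 0.055 and 0.053) or combination replicate 3 (0.062), in a range of 0.00915 to 0.108, and the 2 rises became 1 without combination replicate 2.

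Adding surufatinib to irradiated cells changed 4427 genes against radiation alone, 1802 higher and 2625 lower by limma, a comparison of the drug effect in irradiated cells. The arrestin domain gene ARRDC4 (1.11 ± 0.1) and the noncoding NALT1 (1.21 ± 0.15; its exons overlap MIR4674) rose most, and SNRK-AS1, which overlaps SNRK, fell (-1.05 ± 0.16), beside small RNA genes and a pseudogene. Cholesterol and fatty acid synthesis genes rose in 20 of 31 cases and fell in 0 (21 and 0 adjusted over the list alone), with MSMO1 (0.77 ± 0.07), FDFT1 (0.74 ± 0.06) and SCD (0.68 ± 0.055). Their median was 0.34 (camera adjusted p = 9.63e-12, and adjusted p = 0.0688 with an estimated correlation). NQO1, a quinone reductase gene, rose from 33.0 ± 1.74 to 65.2 ± 1.29 RPKM (SD, n = 3; 0.96 ± 0.05) among 7 higher and 1 lower of 21 NRF2 targets (8 and 1 adjusted over the list alone). Median change was 0.092 (camera adjusted p = 0.0043, and adjusted p = 0.311 with an estimated correlation). SLC2A1 fell from 68.2 ± 5.63 to 32.4 ± 1.92 RPKM (-1.05 ± 0.1) among 16 lower and 0 higher of 23 hypoxia and glycolysis genes, also adjusted over the list alone. The median was -0.267 (camera adjusted p = 2.99e-07, and adjusted p = 0.213 with an estimated correlation). Of 21 integrated stress response genes 14 fell and 0 rose (15 and 0 adjusted over the list alone). Their median was -0.338 (camera adjusted p = 9.29e-07, and adjusted p = 0.213 with an estimated correlation).

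In the same comparison p53 targets rose in 13 of 38 cases and fell in 3 (16 and 5 adjusted over the list alone), with GADD45A (0.68), TP53I3 (0.62) and BAX (0.54) higher. Median change was 0.123 (camera adjusted p = 0.000566, and adjusted p = 0.311 with an estimated correlation). Of 10 NF-kB and inflammatory genes 5 rose and 1 fell, also adjusted over the list alone. The median was 0.189 (camera adjusted p = 0.0154, and adjusted p = 0.311 with an estimated correlation). The 1 fall became 0 without radiation replicate 2 or any 1 combination library. Of 35 G2/M and mitosis genes 0 rose and 14 fell (0 and 15 adjusted over the list alone), CDC25C (-0.85) and CENPF (-0.36) among them. Their median was -0.135 (camera adjusted p = 0.0113, and adjusted p = 0.479 with an estimated correlation). That call was lost without radiation replicate 3 (camera adjusted p = 0.0701; range 3.75e-05 to 0.0701), when 3 genes rose (1 without radiation replicate 2), and the 14 became 9, 8 and 9 without control replicate 3, combination replicate 1 and combination replicate 3. Ribosomal protein genes had 8 higher and 0 lower of 35 (6 and 0 adjusted over the list alone). Median change was 0.172 (camera adjusted p = 1.02e-05, and adjusted p = 0.739 with an estimated correlation). Without radiation replicate 1 their median was 0.065 with 4 higher, and 15 were higher without radiation replicate 3 and 1, 1 and 2 without combination replicates 1, 2 and 3. The split of 1802 higher and 2625 lower genes became 2255 and 2183 under TMM factors. The count was 2613 among the 7421 genes tested with a filter of 5 RPKM, and 2705 when only the 6 libraries compared were fitted.

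Adding radiation to drug-treated cells lowered mitosis and replication genes and raised p53 targets. CCNB1 (chromosome 5, 69167010 to 69178245) went from 39.1 ± 2.65 with surufatinib to 20.4 ± 0.173 RPKM with both (SD, n = 3; -0.90 ± 0.056, limma adjusted p = 5.83e-06). KIF20A (-1.08 ± 0.12), the kinetochore genes CENPW (-1.0 ± 0.12) and SPC25 (-0.99 ± 0.11), and AURKB (-0.95 ± 0.087) fell most. BTBD19 (0.76 ± 0.083) and CD68 (0.74 ± 0.069) were among the larger rises. By limma 1604 genes changed, 748 higher and 856 lower, a split of 653 and 982 under TMM factors and 893 and 806 for RPKM without mitochondrial reads. Of 35 G2/M and mitosis genes 0 rose and 34 fell (0 and 35 adjusted over the list alone). The median was -0.688 (camera adjusted p = 5.58e-51, and adjusted p = 0.000851 with an estimated correlation). Of 37 replication and E2F target genes 0 rose and 32 fell (0 and 35 adjusted over the list alone), including TK1 (-0.87 ± 0.11), FEN1 (-0.72 ± 0.084) and GINS2 (-0.68 ± 0.07). Their median was -0.47 (camera adjusted p = 2.12e-32, and adjusted p = 0.0225 with an estimated correlation). Of 36 double-strand break repair genes 0 rose and 16 fell (1 and 19 adjusted over the list alone), XRCC2 (-0.54) and FANCI (-0.49) among them. Median change was -0.153 (camera adjusted p = 4.72e-09, and adjusted p = 0.0314 with an estimated correlation). Of 38 p53 targets 24 rose and 0 fell (33 and 0 adjusted over the list alone). The median was 0.3 (camera adjusted p = 1.16e-23, and adjusted p = 0.00669 with an estimated correlation). The 1604 genes became 935 with no filter, 2408 with array weights, 961 and 922 without surufatinib replicates 1 and 3, 1041, 1012 and 928 without combination replicates 1, 2 and 3 (318 higher and 610 lower without the last), and 2450 without radiation replicate 1.

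Cholesterol and fatty acid synthesis genes were lower in 15 of 31 cases and higher in 0 against surufatinib alone (17 and 0 adjusted over the list alone), INSIG1 (-0.61 ± 0.087), FDFT1 (-0.53 ± 0.06) and FDPS (-0.43 ± 0.05) most. Their median was -0.221 (camera adjusted p = 4.62e-10, and adjusted p = 0.0314 with an estimated correlation). Without radiation replicate 1, 1 rose. Heat shock genes were lower in 10 of 14 cases and higher in 0 (12 and 0 adjusted over the list alone), with HSPA1A (-0.45), HSPA1B (-0.42) and HSPE1 (-0.36). Median change was -0.228 (camera adjusted p = 6.25e-09, and adjusted p = 0.0314 with an estimated correlation). The 10 became 6 without surufatinib replicate 1. Weaker calls were those of 5 lists. Interferon-stimulated genes had 6 of 23 higher and 0 lower (8 and 1 adjusted over the list alone). The median was 0.098 (camera adjusted p = 0.0276, and adjusted p = 0.193 with an estimated correlation). Integrated stress response genes had 2 of 21 higher and 4 lower (2 and 7 adjusted over the list alone). Their median was -0.102 (camera adjusted p = 0.0329, and adjusted p = 0.486 with an estimated correlation). Senescence-associated secreted factors had 3 of 9 higher and 0 lower, also adjusted over the list alone. Median change was 0.116 (camera adjusted p = 0.0276, and adjusted p = 0.249 with an estimated correlation). Angiogenic ligands had 1 of 12 higher and 0 lower, also adjusted over the list alone. The median was 0.109 (camera adjusted p = 0.0299, and adjusted p = 0.26 with an estimated correlation). Replication-dependent histone genes had 3 of 17 higher and 0 lower, also adjusted over the list alone. Their median was 0.071 (camera adjusted p = 0.0329, and adjusted p = 0.311 with an estimated correlation). Ribosomal protein genes were called with 0 of 35 past the threshold by limma, but not under quantile normalization (0.162; range 5.69e-06 to 0.162). Median change was -0.089 (camera adjusted p = 0.0026, and adjusted p = 0.682 with an estimated correlation). Without radiation replicate 1, 6 fell, and without radiation replicate 3, 1.

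Those 5 weaker calls each ended when single libraries were left out, and 4 of them also in other settings. Interferon-stimulated genes lost theirs without surufatinib replicate 2 (camera adjusted p = 0.054) or combination replicates 1, 2 and 3 (0.0537, 0.0541 and 0.0555; range 0.00486 to 0.0555), with 1, 3, 3, 3, 2 and 0 genes higher without surufatinib replicates 1 to 3 and combination replicates 1 to 3 and a median of 0.049 without the last. Integrated stress response genes lost theirs without surufatinib replicate 3 (0.0961, median -0.063), combination replicate 2 (0.0618) and combination replicate 3 (0.0744). They also did so with TMM factors (0.0535, median -0.124), and with a length trend (0.0521, median -0.082) or a length and GC trend (0.063, median -0.092) removed (range 0.0101 to 0.0961). Their 4 falls became 7 without radiation replicate 1 and 2 without surufatinib replicates 1 or 3 or combination replicates 1 or 2. Their 2 rises became 0 without surufatinib replicate 1 or combination replicates 2 or 3, and 1 without any other library but radiation replicates 1 and 2. Senescence-associated factors lost theirs without surufatinib replicate 3 (0.0913) and combination replicate 1 (0.0775), without replicates 1 of radiation and combination (0.0722), and with no filter on low values (0.23, median 0.014; range 0.00214 to 0.23). Angiogenic ligands did so without surufatinib replicate 3 (0.0593) and combination replicate 1 (0.0627), without replicates 1 of radiation and combination (0.0529), with no filter (0.23, median 0.024) and among genes of at least 5 RPKM (0.11; range 0.0208 to 0.23), and 2 rose without radiation replicate 1. Histone genes did so without surufatinib replicate 3 (0.102) and combination replicates 1 and 2 (0.0627, median 0.111, and 0.0618), without replicates 1 of radiation and combination (0.0529, median 0.111), with no filter (0.266, median 0.02) and for RPKM without mitochondrial reads (0.0781; range 0.0149 to 0.266), and their median was 0.14 without surufatinib replicate 2.

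**Figure D3:**
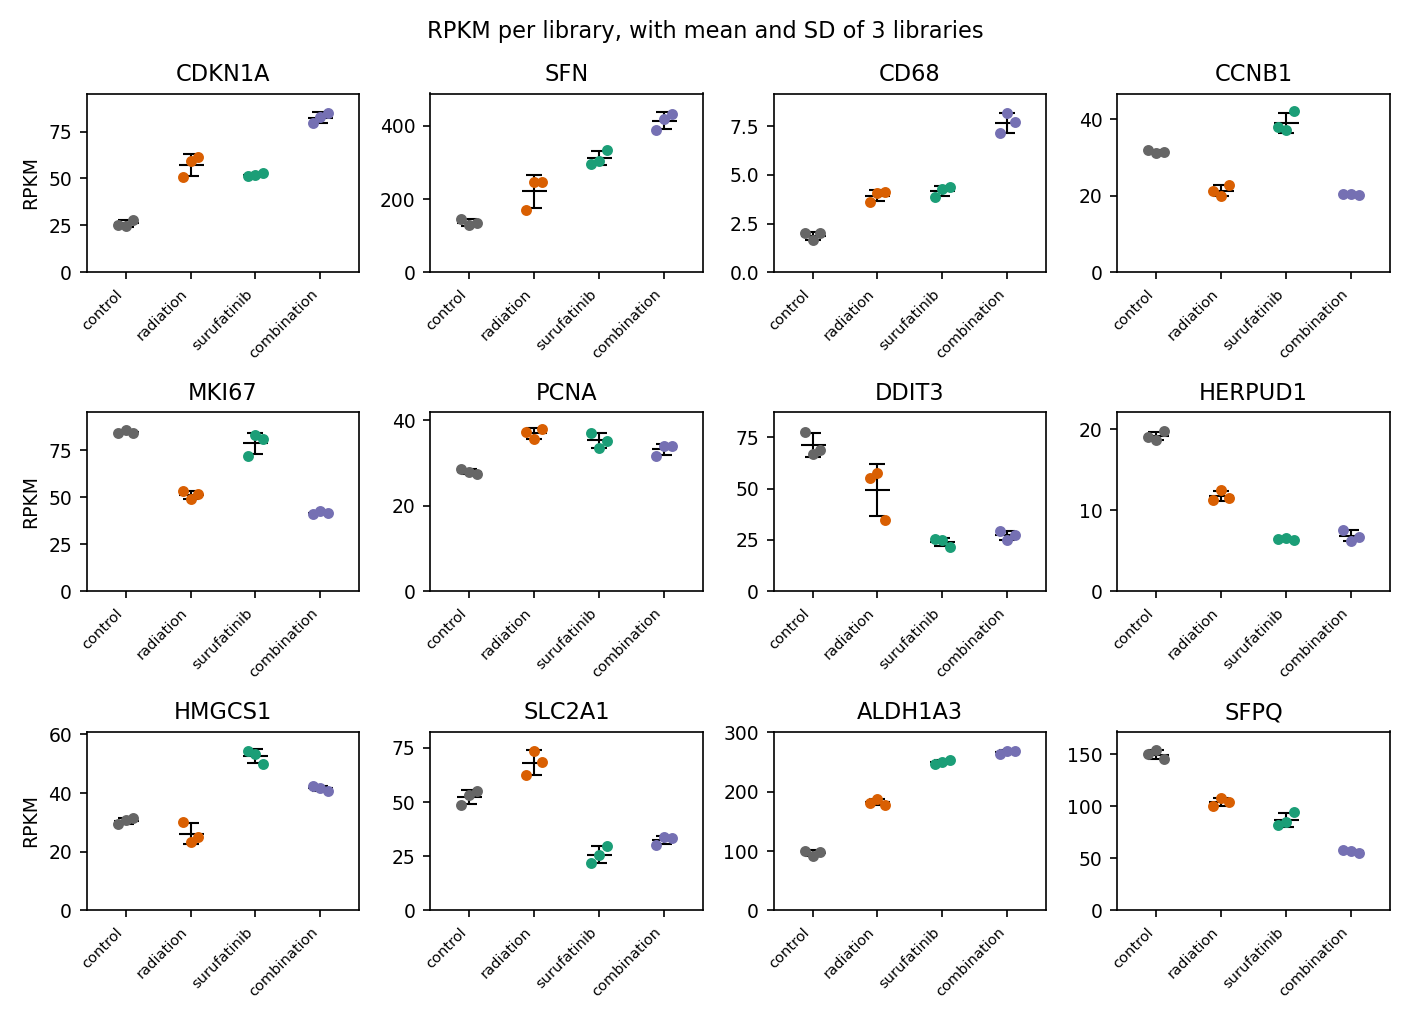
RPKM of 12 genes in each of the 12 libraries, as points grouped by treatment, with the group mean (long dash) and SD (whiskers, n = 3); each axis starts at 0. CDKN1A goes from 26.0 RPKM in control to 82.4 with both treatments, CD68 from 1.88 to 7.66, and ALDH1A3 lies at 250 with the drug alone and 267 with both.

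Whether the 2 treatments together differ from the sum of their log2 effects was tested as an interaction, and few single genes passed. By limma 8 genes passed, 1 above and 7 below 0, with 1300 at an unadjusted p under 0.05. Simulated 1.5-fold and 2-fold interactions were recovered in 55.4% and 82.8% of cases. Those simulations held no deviating library and gave genes of similar level the same spread, so the real shares may be lower. Each also held 200 changed genes. With as few calls as the 8 here the adjusted threshold is stricter, so these shares do not measure what was missed. ALDH1A3 rose with radiation alone (0.91) and with drug alone (1.36) but radiation added to the drug gave 0.09 ± 0.045, an interaction of -0.82 ± 0.063 (limma adjusted p = 0.000579). RP11-66B24.8 and RP11-66B24.4, whose exons overlap it, are 2 of the other genes called, and their reads are uncertain. HERPUD1 fell with either treatment and by no more with both, an interaction of 0.73 ± 0.086 (limma adjusted p = 0.00884). ORC6, a subunit gene of the replication origin complex, stood at 5.56 ± 0.143, 5.10 ± 0.102, 8.23 ± 0.141 and 4.95 ± 0.158 RPKM in control, radiation, surufatinib and combination (SD, n = 3), with an interaction of -0.53 ± 0.055 (limma adjusted p = 0.00305). PCNA (-0.47 ± 0.069, limma adjusted p = 0.0444), the paraspeckle gene PSPC1 (-0.45 ± 0.06, 0.0294) and the spindle gene NUSAP1 (-0.40 ± 0.055, 0.0314) were nearer the threshold. PCNA and PSPC1 lost their calls without any 1 library but radiation replicate 1, and NUSAP1 without any but radiation replicate 1 and surufatinib replicate 3. The highest adjusted p, 0.15 for each, came without combination replicate 2 (ranges 0.0153, 0.00589 and 0.00589 to 0.15). The 8 genes became 5 without control replicates 1, 2 or 3, radiation replicate 3, surufatinib replicate 2 or combination replicates 2 or 3, 16 without radiation replicate 1, 13 among genes of at least 5 RPKM, 52 with array weights and 15 with voom. With a length and GC trend removed, a setting that tested only the 12376 genes with a GC value, they became 18, 6 higher and 12 lower.

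As lists, the mitosis genes and, at the preset correlation only, the replication genes lay below 0, so they fell more with radiation in drug-treated cells. Their median changes with radiation were -0.443 and -0.225 without the drug and -0.688 and -0.47 with it. The drug alone had medians of 0.208 and 0.155 against control, and the combination had -0.135 and -0.109 against radiation alone. With an estimated correlation neither list was called for the drug alone (camera adjusted p = 0.235 and 0.566) or against radiation alone (0.479 and 0.745). Against radiation alone the replication list was not called at the preset correlation either (0.0571). The G2/M and mitosis genes had a median interaction of -0.235, with 0 above and 1 below 0 past the threshold and 0 and 17 adjusted over the list alone (camera adjusted p = 9.26e-26, and adjusted p = 0.00953 with an estimated correlation). The replication and E2F target genes had a median of -0.234, with 0 and 1 past it and 0 and 16 adjusted over the list alone (camera adjusted p = 4.33e-18, and adjusted p = 0.111 with an estimated correlation). The unfolded protein response genes lay above 0 (median 0.239; 1 and 0, 9 and 0 adjusted over the list alone; camera adjusted p = 1.09e-14, and adjusted p = 0.104 with an estimated correlation). The 1 mitosis gene past the threshold became 2 without radiation replicate 1, and 0 without each other library but radiation replicate 2 and surufatinib replicate 3. The 1 replication gene became 3 without radiation replicate 1 and 0 without each of the other 11.

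The response to radiation went largely the same way in cells without and with the drug, as measured in comparisons that have no library in common. Across 15387 genes, which are not independent replicates, log2 changes of radiation against control and of combination against surufatinib had a Pearson r of 0.561 and a Spearman rho of 0.57. Their signs were the same for 71.4% of these genes. Of 1665 and 1604 genes called, 823 were called in both, 822 of them in the same direction, 381 higher and 441 lower, where independent lists would share 42 and 45. Both comparisons use the same variance per gene from 1 fit, so some sharing beyond independent lists could arise from that alone. For the drug effect without and with radiation r was 0.75 and rho 0.752, and signs were the same for 79.9% of all genes. In both 3131 genes were called, 3120 in the same direction, 1261 higher and 1859 lower against 253 and 474 for independent lists, with the same limit.

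The drug's receptor targets other than FGFR1 were little expressed in these cells. Of 33 macrophage factors 12 passed the filter, some at high levels, such as HMGB1 at 104 ± 6.21 RPKM in control (SD, n = 3). Of the 5 target receptor genes only FGFR1 passed the filter on low values, at 4.57 ± 0.311, 4.55 ± 0.23, 3.83 ± 0.141 and 4.33 ± 0.222 RPKM in control, radiation, surufatinib and combination (SD, n = 3). It fell with surufatinib (-0.20 ± 0.055, limma adjusted p = 0.0153), a call lost without control replicate 2 (0.0625), control replicate 3 (0.0627) or surufatinib replicate 1 (0.0581) and with a length trend removed (0.157; range 0.00374 to 0.157). Of 12 tested macrophage-recruiting and M2-polarizing factors, radiation raised 0 and lowered 1, HMGB1 (-0.55 ± 0.049), a nuclear protein gene whose product can be released as an alarm signal, and the combination raised 0 and lowered 3, among them the osteopontin gene SPP1 (-0.63 ± 0.082) and HMGB1 (-0.36 ± 0.049). Surufatinib alone raised 2 and lowered 1, SPP1 (-0.52 ± 0.082). The combination raised 2 and lowered 2 against radiation alone, and raised 0 and lowered 1 against surufatinib alone. Mean HMGB1 was 104 ± 6.21, 70.5 ± 1.97, 115 ± 2.79 and 80.3 ± 1.55 RPKM in control, radiation, surufatinib and combination, so its mean was higher with the drug than without it. Without any 1 control library SPP1 (1.12 ± 0.0961 RPKM in control) no longer met the filter, and the falls became 0 with surufatinib and 1 with both. The 2 rises with surufatinib became 0 without control replicates 2 or 3 or surufatinib replicates 1 or 2, 1 without surufatinib replicate 3 or any 1 combination library, and 4 without radiation replicate 1. Without radiation replicate 3, 1 factor rose with radiation, and without radiation replicate 1, 1 rose with both. Adjusted over the list alone these counts were 2 higher and 3 lower for radiation, 0 and 2 for the combination and 2 and 1 for surufatinib, and camera called the list in none of the 5 comparisons (adjusted p from 0.365 to 0.805). By fry's directional test, not against other genes, members were lower with radiation (adjusted p = 0.0227), the combination (0.0125) and combination against surufatinib (0.0286). That test did not pass for surufatinib (0.648) or combination against radiation (0.759). TGFB1 (9.67 ± 0.268 RPKM in control) and VEGFA (14.2 ± 0.155) did not pass by limma in any of the 5 comparisons, and CSF1, CCL2 and IL6 were below the filter, CSF1 at 0.613 RPKM in control cells.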

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

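The results taken up here are those of the interaction, picked out because they ask whether one effect differs between groups; the removal of length and GC trends, the regrouping with both effects taken out and the fit without radiation replicate 1 as an explanation of the mitosis genes were tests chosen after results were seen. By limma 8 genes were called, with 1300 at an unadjusted p under 0.05. In the simulations, which held 200 changed genes each and no deviating library, 55.4% of 1.5-fold interactions were recovered. The share may be lower where fewer genes change. The paths of the 8 differ: ALDH1A3 (-0.82) rose with each treatment and stayed near the level of the drug alone with both, at 250 ± 3.78 and 267 ± 3.52 RPKM (SD, n = 3). HERPUD1 (0.73) was lowered by each treatment and lay at 6.44 ± 0.104 RPKM with the drug and 6.85 ± 0.687 with both. ORC6 (-0.53), PCNA (-0.47) and NUSAP1 (-0.40), which serve replication and the spindle, had higher means with the drug alone than in control and lower means with both than with the drug alone, and the paraspeckle gene PSPC1 (-0.45) was lower with both, at 15.7 ± 0.279 RPKM against 23.5 ± 0.798 in control.

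The calls of ALDH1A3, HERPUD1 and ORC6 held in every alternative run (limma adjusted p from 3.16e-06 to 0.00558, from 0.000209 to 0.0499 and from 0.000466 to 0.0229). Those of PCNA, PSPC1 and NUSAP1 did not: without combination replicate 2, for example, each had an adjusted p of 0.15, and without radiation replicate 1 each passed. When the 12 libraries were regrouped in 100 ways, the real one included, 1 gave as many as 8 genes, the real one, and the highest other count was 1, but this decides nothing, since the other groupings put the effects of the treatments into the residual (median residual SD 0.137 against 0.0857). With the sum of both effects taken out first, 1 of the same 100 gave as many as 8, the real one, and the highest other count was 2, so a random grouping is excluded for this count.

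Of the lists, p53 targets (median interaction -0.075), G2/M and mitosis genes (-0.235), replication and E2F targets (-0.234) and double-strand break repair genes (-0.094) lay below 0, and replication-dependent histone genes (0.117), unfolded protein response genes (0.239) and ribosomal protein genes (0.107) above. By camera the p53 list had an adjusted p of 0.00067 (0.371 with an estimated correlation) with 0 of 38 genes past the threshold by limma, 1 without radiation replicate 1, and 0 above and 1 below 0 adjusted over the list alone. The repair list had 9.43e-05 (0.208 with an estimated correlation), 0 of 36 genes past it and 5 below 0 adjusted over the list alone, and was not called among genes of at least 5 RPKM (0.773, median -0.001; range 7.25e-06 to 0.773). The ribosomal list had 0.000139 (0.812 with an estimated correlation) and was not called without radiation replicate 1 (0.639, median -0.001) or without it and combination replicate 1 (0.622, median 0.007; range 1.71e-08 to 0.639), so it rests on that library. The histone list had 0.0246 (0.371 with an estimated correlation) and was not called without control replicate 1 (0.0988), radiation replicate 1 (0.205, median 0.071), surufatinib replicate 3 (0.146), combination replicate 1 (0.0929) or both replicates 1 of radiation and combination (0.4, median 0.027), nor with no filter on low values (0.441, median 0.014; range 0.00761 to 0.441). The mitosis list held with an estimated correlation (camera adjusted p = 0.00953), while the replication list (0.111) and the unfolded protein list (0.104; range at the preset correlation 5.68e-16 to 2.22e-10) did not.

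For the G2/M and mitosis genes 3 technical explanations were tested. The deviating radiation replicate 1 is excluded as the whole cause, since the median without it was -0.243 (camera adjusted p = 4.69e-18; range 1.39e-31 to 3.12e-17). A gene length trend between libraries is excluded in the same way, with a median of -0.231 once it was removed, and so is a GC trend, with -0.241 once length and GC were removed. No biological explanation was tested, since these data hold no cell cycle measurement and RNA was taken at 24 h only.

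For the 5 pair comparisons the 6 libraries make 10 splits, too few for a share under 0.05. In each the real grouping was 1 of 10 with as many genes: 1665 for radiation, 4937 for surufatinib, 6144 for the combination, 4427 for combination against radiation and 1604 for combination against surufatinib, where the highest other split gave 0, 0, 0, 0 and 1. These low counts decide nothing, since every other split mixes libraries of both groups and so puts their difference into the residual.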

How the results depend on the processing

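Chosen after seeing the data were voom on recovered reads, removal of a length or a length and GC trend, RPKM without mitochondrial reads, and leaving out radiation replicate 1 with combination replicate 1; the other settings were planned. The tests planned in case the file held raw counts were not run, since it holds none. Of 509 gene results called, 388 kept their call in every alternative in which the gene was tested, and 792 of 13571 called values under alternatives lost it; of 57 list calls 39 did so, with 54 of 1423 values lost. The filter of 5 RPKM tested only 7421 genes and the fit with no filter 48085, against 15387, so counts in those settings cover other sets of genes. The cause of the other changes below was not tested.

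The radiation count of 1665 moved to 1005 with no filter on low values, 652 with only the 6 libraries compared and 2852 with array weights, and lay between 894 and 1977 with 1 library left out. With an RPKM of at least 5 in at least 3 libraries, and so only 7421 genes tested, the surufatinib count of 4937 moved to 2920 and the combination count of 6144 to 3451. Of these, 2810 and 3337 were also called with the filter of 1 RPKM. With 1 library left out the 2 counts lay between 3511 and 6104 and between 4843 and 7144. Combination against radiation, 4427, moved to 2613 with an RPKM of at least 5 and 2705 with only the 6 libraries compared, and lay between 3073 and 4338. Combination against surufatinib, 1604, moved to 935 with no filter and 2408 with array weights, and lay between 922 and 2450. The interaction count of 8 moved to 13 with an RPKM of at least 5, 52 with array weights and 15 with voom, and lay between 5 and 16 with 1 library left out. It moved to 18 with length and GC trend removed, where only 12376 genes were tested.

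The correlation of the radiation effect without and with surufatinib, 0.561, moved to 0.432 with a pseudocount of 0.1, 0.422 with no filter, 0.708 with an RPKM of at least 5, 0.451 with voom and 0.502 without radiation replicate 1 and combination replicate 1, and lay between 0.506 and 0.567 with 1 library left out. That of the surufatinib effect, 0.75, moved to 0.667, 0.641, 0.834, 0.687 and 0.702 in the same settings, and lay between 0.711 and 0.744.

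Of the named genes, 1 changed sign after a call: MT-ND3 in combination against control, 0.42 (limma adjusted p = 0.0185), was -0.044 (0.66) under quantile normalization (range 0.00147 to 0.66). The median interaction of the mitochondrially encoded genes, 0 (camera adjusted p = 0.854), was -0.096 without radiation replicate 2 and 0.158 (0.00643) without radiation replicate 1, the library with the highest mitochondrial share.

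Replicate numbers did not pair the libraries: residual correlations between libraries of the same number had a median of 0.026, against -0.018 for other numbers, and 2 of 18 exceeded 0.1. With a replicate block the counts were 1721, 5101, 6338, 4597, 1623 and 7 in the order above, and the heat shock genes were not called in combination against control (camera adjusted p = 0.0686; range 0.00915 to 0.108).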

Other observations

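The test of macrophages in the cultures was chosen after results were seen, as was the interval for gene span; the other tests here were written before their results. Apart from FAS, the single genes named in this paragraph belong to lists that camera called in no comparison with control. Of 29 ERK output genes 7 rose and 14 fell with both treatments (7 and 15 adjusted over the list alone), FOSL1 (0.82 ± 0.042) among those higher and FOS (-1.07 ± 0.074) among those lower, and the 14 became 9 without combination replicate 2. The growth factor receptor IGF1R was lower with the drug (-0.59 ± 0.047) and with both (-0.61 ± 0.047). Of 6 xenobiotic response genes 4 rose and 1 fell after surufatinib and 3 rose and 1 fell with both, also adjusted over the list alone (medians after radiation, surufatinib and both -0.069, 0.24 and 0.125; camera adjusted p = 0.183, 0.0643 and 0.259). After surufatinib the efflux pump gene ABCB1 fell (-0.46 ± 0.051) while TIPARP rose (0.35 ± 0.058). The contractile gene ACTA2 rose in the combination (1.4 ± 0.076), though its exons overlap FAS, itself a p53 target. E-cadherin, CDH1, fell with the drug (-0.58 ± 0.059) and the bile duct keratin KRT19 rose (0.43 ± 0.11).

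Other lists that camera called in no comparison with control are given by their medians after radiation, surufatinib and combination, since many of their counts of passing genes moved by over 1.5 times when 1 library was left out. Apoptosis regulators (25 genes) had medians of 0.041, 0.009 and 0.08 (camera adjusted p = 0.0982, 0.28 and 0.12), other receptor tyrosine kinases (15) of -0.018, -0.072 and -0.069 (0.973, 0.221 and 0.313), and ERK output genes (29) of -0.064, -0.11 and -0.148 (0.736, 0.273 and 0.486). Epithelial-mesenchymal transition genes (18) had 0.025, -0.119 and -0.119 (0.579, 0.251 and 0.499), epithelial and cholangiocyte identity genes (12) 0.096, 0.059 and 0.057 (0.275, 0.838 and 0.607), and antigen presentation genes (20) -0.012, 0.004 and 0.006 (0.609, 0.805 and 0.607). Autophagy and lysosome genes (21) had -0.025, -0.064 and -0.118 (0.877, 0.108 and 0.368), ferroptosis regulators (18) 0.02, 0.021 and 0.118 (0.661, 0.676 and 0.287), and mitochondrially encoded genes (13) 0.027, -0.08 and -0.097 (0.546, 0.581 and 0.849). Replication-dependent histone genes (17), which camera called in combination against surufatinib and in the interaction, had -0.025, -0.083 and 0.026 (0.985, 0.581 and 0.56). The mean had the other sign for the receptor kinases after radiation (0.012) and, after surufatinib, for the identity (-0.027) and antigen presentation genes (-0.006). Too few markers were expressed to test as lists: 1 of 17 for macrophages (CD68), 0 of 13 for lymphocytes, 1 of 10 for fibroblasts (COL1A1, -0.61 ± 0.068 in the combination), 0 of 10 for endothelium and 3 of 12 for hepatocytes, with SERPINA1 at 0.34 ± 0.083 in the combination.

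The first pattern is that surufatinib log2 changes fell with exonic gene length (Spearman rho -0.29 over 10786 protein-coding genes; 516 higher and 199 lower in the shortest of 5 length groups, 161 and 714 in the longest). Variation from library to library is argued against, as 6 of 6 libraries with drug had a length slope below all 6 without; so are GC content (rho -0.248 at fixed GC) and low expression (rho -0.313 among genes with a mean of at least 5 RPKM). Genomic span and exonic length cannot be told apart: rho with span at fixed length was -0.164, with length at fixed span -0.142, and the difference of sizes, 0.022, had a bootstrap 95% interval of -0.0123 to 0.0558. A difference in RNA integrity that goes with the drug could give the same trend and stays open, since it would be confounded with treatment. The groups described for the drug may carry part of it. With a length trend removed 1 list call was lost, and with length and GC removed 2, none of them in surufatinib against control. The split of genes changed by surufatinib, 2160 higher and 2777 lower, became 2213 and 2540 with the length trend removed. With length and GC removed it was 2338 and 2427 among the 12376 genes with a GC value.

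The second pattern is that CD68 rose with each treatment. Macrophages in the cultures are argued against: 0 of 16 other macrophage markers reached 0.5 RPKM in the combination, the highest being LYZ at 0.297 RPKM, with TYROBP at 0.0142, FCER1G at 0.159 and LAPTM5 at 0.11. For reads of an overlapping gene, 0 overlapping genes reached 1 RPKM with at least 0.5 of the CD68 log2 change: RP11-186B7.4 changed by 0.04 and AC113189.5 by 0.32. This cannot decide the question, since RP11-186B7.4 stood at 63.4 RPKM in control and 65.3 RPKM with both treatments, far above CD68. A small share of its reads could make up the CD68 rise without a large log2 change of its own. What raised CD68 in these cells was not tested, and the autophagy and lysosome list was not called.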
